A study of Homo sapiens with 70 samples.

How the data were processed

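Peak lists of 48 of the 70 libraries of the series were analysed, 20 of nascent strands and 28 of ChIP-seq, all from HCT116 cells. The other 22 libraries (genomic DNA, input and method controls among them) have no list used here. Groups and replicate numbers came from the labels. For 1 library the title names another MCM2 residue than the antibody label, and the antibody label was used (pS53-MCM2, H363Y). Per the submitters' processing notes, the tools included MACS2 and R 3.5.1 and the genome build was hg19. Each list belongs to 1 library, so that replicates were called separately. The aligner, the control library behind each list and the calling settings are not given in the sources used here.

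Nascent-strand lists and the pS139-MCM2 lists of MCM2-mAID cells held, as deposited, a score, a fold enrichment over background (a linear ratio) and the −log10 of a p-value and of a q-value per peak, calculated by the authors. These are the authors' values for single peaks and served only to rank, filter or describe peaks within a list. ChIP lists of the SIRT1 set held positions only, so that width took the place of strength there. The lowest −log10 q in a deposited list was between 2.09 and 3.72 in nascent-strand lists of the SIRT1 set, between 2.00 and 2.02 in those of the MCM2 set, and between 1.30 and 1.31 in MCM2-set ChIP lists, so thresholds differ between sets and between lists.

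Peaks on chromosomes 1 to 22 and X were kept. In nascent-strand lists of the SIRT1 set, several peaks (summits) can share 1 interval. Peak number counts every line, and set operations used distinct intervals. An overlap of 1 bp counted as shared. Baseline origins were merged regions called in both untreated WT libraries. Induced origins were called in both libraries of a group and touched no peak of either untreated WT library. For ChIP and MCM2 add-back comparisons, induced origins were those called in both KO and both H363Y libraries and in neither WT library. Positions are 1-based, on hg19.

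The preference of a ChIP list for baseline origins was the Mantel-Haenszel log2 odds ratio of a baseline against an induced origin being touched, over deciles of origin width, with a Robins-Breslow-Greenland counting SE. Groups were compared by exact permutation over all distinct partitions of the libraries. Shuffles (100) placed regions at random within their chromosome, outside untreated WT peaks for overlaps of induced origins. They did not avoid assembly gaps. Unchanged groups were simulated from 1 pool of 110927 sites with the detection rates implied by the overlap of the untreated WT libraries, 35.4% and 40.3%. A second simulation, added after seeing the data, set the rates by the number of intervals in each list over that pool. Depth is unknown because the lists hold no read counts. Precision is therefore given as the spread of 2 libraries or, for shares of regions, as 95% Wilson intervals that cover counting error only. Work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Interval and test code was tested on simulated data: overlaps matched a brute-force count in 100% of intervals, and planted log2 odds ratios were recovered with a mean error of 0.01.

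Named regions followed a rule set before the data were examined: the 5 baseline and 5 induced origins with the highest mean of the authors' fold enrichment, and the 5 pT530-SIRT1 regions called in both WT libraries and neither KO library with the largest mean, over both, of the widest peak. The rule also named genes and gene lists (known origins, fragile sites, replication, housekeeping, colon epithelium, other lineages, HOX, olfactory receptor and histone genes). These were not analysed here, because no hg19 annotation was used and positions were not converted between builds. Alternatives were stricter peaks, an overlap of 50% of the shorter region, equal numbers of strongest peaks, a 5 kb distance from WT peaks, 2 kb windows, aphidicolin-induced origins, peaks within 1 kb merged, covered bases, each replicate left out and the replicate number as a block. Alternatives added after seeing the data were distinct intervals, 500 bp windows on summits, removal of chromosomes 5, 9, 12 and X, removal of origins at negative-control peaks, a split by the shortest peak of a list, and each untreated WT replicate left out for the preferences of single MCM2 antibodies.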

Results

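Replication origins were mapped in HCT116 cells, a human colon carcinoma line, by sequencing short nascent DNA strands left after lambda exonuclease digestion, which removes DNA without the RNA primer that protects newly started strands. The series also mapped chromatin sites of phosphorylated SIRT1, a protein deacetylase, and of phosphorylated MCM2, a subunit of the replicative helicase, by chromatin immunoprecipitation and sequencing (ChIP-seq). Its title names the question: how SIRT1 and the checkpoint kinase ATR act on dormant origins, which are licensed but do not start replication in an unperturbed cell cycle. Peak lists of 48 libraries were analysed, 20 of nascent strands and 28 of ChIP. The first set compared cells with wild-type (WT) SIRT1, SIRT1 knockout (KO) and the H363Y form of SIRT1, and WT cells given 0.8 µM aphidicolin, a DNA polymerase inhibitor, for 24 h. The second set used MCM2-mAID cells, in which the label names a degron-tagged MCM2, with no add-back or with WT, S139A, S139D, S108A or S108D MCM2. Nascent-strand groups had 2 libraries each. ChIP groups had 2, except for pS53-MCM2 and pS40/41-MCM2 with 1 per genotype. All cells received 5 nM trichostatin A, a histone deacetylase inhibitor, for 24 h per the labels. Per the labels, cells for pT530-SIRT1 ChIP were asynchronous and those for MCM2 ChIP were held at the G1/S boundary by a double thymidine block. The lists hold no read counts, so the depth of each library is unknown, and the number of peaks depends on it. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries.

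SIRT1 knockout nascent strands gave about 2 times as many peaks as WT. WT libraries held 73198 ± 3526 peaks (SD, n = 2), KO libraries 150798 ± 7373 and H363Y libraries 100614 ± 6816. Aphidicolin-treated WT libraries held 81464 ± 20457. KO peaks covered 86.2 ± 8.51 Mb of the genome against 35.5 ± 1.58 Mb in WT, 62.4 ± 19.7 Mb in H363Y and 34.3 ± 6.73 Mb under aphidicolin. The difference of mean log2 peak number from WT was 1.04 ± 0.10 for KO, 0.46 ± 0.12 for H363Y and 0.13 ± 0.37 for aphidicolin, where the error combines the SDs of both groups. Over the 4 groups, group explained 0.894 of the variance of log2 peak number (two-sided exact permutation test, p = 0.0667), which does not pass 0.05. The test passed for covered bases (p = 0.0286, exact permutation) and without aphidicolin replicate 1 (p = 0.0286) or replicate 2 (p = 0.019). It did not pass for distinct intervals (0.643, exact permutation p = 0.238), above a common fold enrichment or with merged peaks (p = 0.0762 each), or without any of the 6 other libraries (p from 0.0667 to 0.0952). A pair of groups of 2 cannot give an exact p below 0.333. Above a common fold enrichment the difference was 1.71 ± 0.19 for KO, -0.041 ± 1.01 for H363Y and 0.59 ± 0.30 for aphidicolin, and with peaks within 1 kb merged it was -0.33 ± 0.43, 0.34 ± 0.25 and 0.52 ± 0.28. All 3 differences therefore depended on the measure. Several peaks of a list can share 1 interval, and in distinct intervals the KO difference was -0.20 ± 0.50 on the log2 scale, within the replicate spread (37995 ± 12379 intervals in KO, 42565 ± 4653 in WT). H363Y lists held 57259 ± 6633 intervals and aphidicolin lists 58192 ± 9740, each list above both WT lists, so the order of the groups changed. KO intervals held 4.16 ± 1.16 peaks each, against 1.73 ± 0.11 in WT, 1.76 ± 0.09 in H363Y and 1.39 ± 0.12 under aphidicolin.

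**Figure D1:**
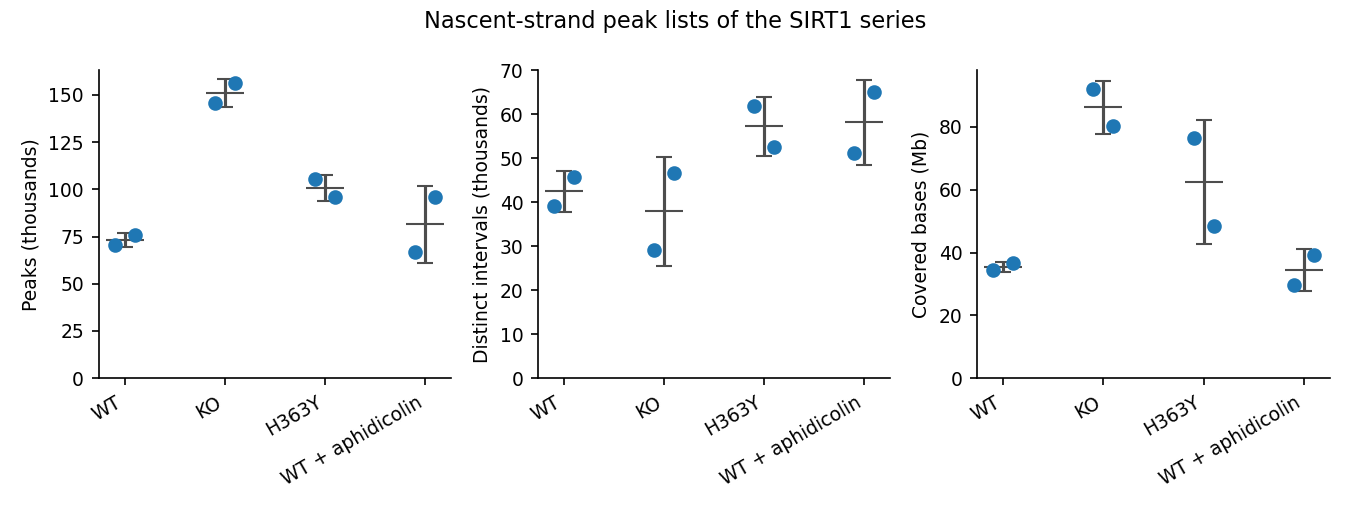
Number of peaks, number of distinct intervals and covered bases in Mb of each nascent-strand list of the SIRT1 series; points are libraries, bars the mean and lines the SD (n = 2). KO lists hold 145585 and 156012 peaks, above all other lists, while their 29242 and 46748 intervals lie on both sides of the 39274 and 45855 of WT.

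Replicates of KO shared most of their covered bases of any replicate pair in this set, with a Jaccard index (shared over joint bases) of 0.482. The index was 0.304 for the aphidicolin replicates, 0.262 for H363Y and 0.204 for untreated WT. WT replicate 1 shared more with H363Y replicate 2 (0.286) and with KO replicate 2 (0.247) than with the other WT replicate. Aphidicolin libraries stood apart, with indices of 0.0815 to 0.12 to the 6 other lists. The mean index within groups exceeded that between groups by 0.153 (two-sided exact permutation test, p = 0.00952). Without KO replicate 1 the difference was 0.0961 (p = 0.0857, exact permutation). List size caps this index, and the lists covered between 29.6 and 92.2 Mb, so these values do not separate list size from position.

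Baseline origins, called in both untreated WT libraries, numbered 14873, with a median width of 1095 bp and a median gap of 22.04 kb. Of these, 60.1% were called in both H363Y libraries, 52.7% in both KO libraries and 33.1% in both aphidicolin libraries, and 2691 in all 8 lists of the set. Baseline origins were densest on chromosomes 12 (136 per 10 Mb), 19 (131), 9 (119), 17 (113) and 22 (111). Chromosome X had 57.3 per 10 Mb and chromosome 2 had 20.8. Untreated WT lists had 12.8 ± 0.322% of covered bases on chromosome 9, 12.3 ± 0.668% on chromosome 12 and 5.86 ± 0.0571% on chromosome X. Under aphidicolin these shares were 2.21 ± 0.00424%, 3.95 ± 0.0863% and 0.481 ± 0.0317%, and the share of chromosome 2 was 9.81 ± 0.0814% against 3.44 ± 0.247% untreated (n = 2 in each group). The 5 baseline origins with the highest mean of the authors' fold enrichment lay, on hg19, at chromosome 4 from 49322553 to 49323669 (fold 101), chromosome 4 from 9273389 to 9273916 (60.7), chromosome 4 from 9325959 to 9326358 (38.9), chromosome 2 from 3698828 to 3699206 (35.7) and chromosome 10 from 42817324 to 42818260 (35.2). The first of these was called in all 8 lists of this set and all 12 of the MCM2 set. It was also touched by a peak in all 22 ChIP lists of the SIRT1 set other than the knockout pT530-SIRT1 lists. Calls alone do not tell such a site from one that gives signal in any assay. The last of the 5 touched a pT530-SIRT1 peak of the knockout, which is the negative control.

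**Figure D2:**
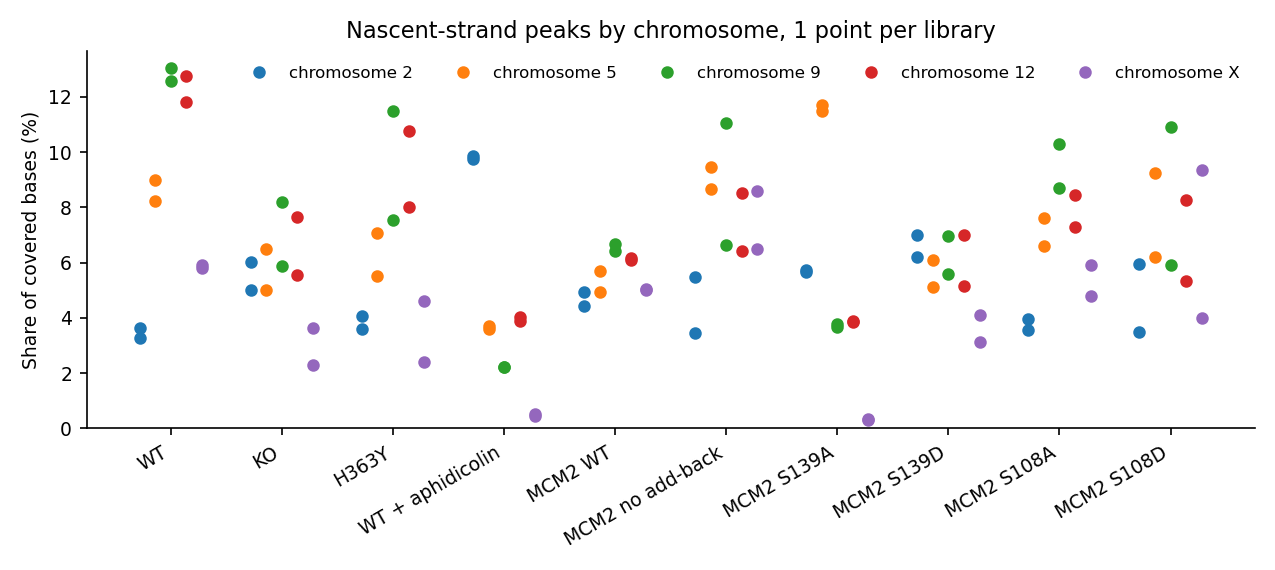
Share of covered bases on chromosomes 2, 5, 9, 12 and X in each of the 20 nascent-strand lists, in percent; each point is 1 library. The X share is between 0.291% and 0.503% in the aphidicolin and S139A lists and between 2.29% and 9.36% in the others.

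Induced origins were regions called in both libraries of a group that touched no peak of either untreated WT library. KO gave 6600 of them (median width 2532 bp), H363Y 6194 (1253 bp) and aphidicolin 19337 (664 bp). Unchanged groups simulated with the detection rates of the untreated WT libraries gave 6113 such regions by the same rule. With rates set by list sizes they gave 4668 for KO, 11129 for H363Y and 11399 for aphidicolin. The KO count lay near the first value and above the second, and the H363Y count near the first and below the second. Counts alone therefore do not show that either genotype induced origins. A group of 1242 regions was called in both KO and both H363Y libraries and in no untreated WT library, with a median width of 3329 bp, and 35.5% of these were also called in both aphidicolin libraries. The 5 of them with the highest mean of the authors' fold enrichment lay, on hg19, at chromosome X from 153880086 to 153882089 (fold 14.2), chromosome 15 from 74902126 to 74909632 (12.3), chromosome 5 from 31639473 to 31643149 (10.9), chromosome 11 from 67170561 to 67181096 (10.9) and chromosome 7 from 149743990 to 149744713 (10.8). Each was called in at least 10 of the 12 nascent-strand lists of the MCM2 set. The first was also touched by a peak in all 22 ChIP lists of the SIRT1 set other than the knockout pT530-SIRT1 lists. Counts of induced origins depended on single libraries. Without KO replicate 1 the KO count was 22504, without KO replicate 2 it was 13544 and without WT replicate 1 it was 11035. The H363Y count was 22142 and 34340 without its own replicates 1 and 2, and 10555 and 10561 without WT replicates 1 and 2. The aphidicolin count was 45901 and 34636 without its own replicates 1 and 2.

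KO-induced origins met H363Y-induced origins more often than shuffled positions did. Of the 6600, 1290 (19.5%, 95% Wilson interval 18.6% to 20.5%) touched an H363Y-induced origin, against 1.02 ± 0.117% over 100 shuffles within chromosomes outside WT peaks, a ratio of 19.3. A simulation of unchanged groups with the detection rates of the WT libraries gave 14.3 ± 0.413%, and independent lists drawn from the 53302 candidate regions would share 11.6%. With detection rates set by each group's own list sizes, unchanged groups shared 26.4 ± 0.614%, so whether the overlap exceeded that of unchanged groups depended on the simulation. The last one gave 4668 KO-induced and 11129 H363Y-induced regions, where 6600 and 6194 were observed. In the other direction, 1350 (21.8%) of the H363Y-induced origins touched a KO-induced origin. That share lay above the 14.3 ± 0.413% of the first simulation, the 11.1 ± 0.286% of the second and the 12.4% of independent lists. The second simulation shares the same regions in both directions, so its 2 shares differ only through its set sizes, 4668 and 11129. These are not the observed 6600 and 6194. Its shares therefore cannot be set directly against the observed ones, and the change with direction is not a result about the origins. Of the KO-induced origins, 1521 (23.05%, Wilson interval 22.05% to 24.1%) touched an aphidicolin-induced origin, against 2.59 ± 0.187% when shuffled, a ratio of 8.91. Independent lists would share 28.0% there and unchanged groups of these list sizes 27.1 ± 0.641%, and the observed overlap lay below both. It lay above the 14.3 ± 0.413% of unchanged groups with the detection rates of the WT libraries. In the other direction, 8.85% of aphidicolin-induced origins touched a KO-induced origin, below 9.56% for independent lists and 14.3% and 11.1% in the first and second simulation. For this pair the second simulation gave 4668 KO-induced and 11399 aphidicolin-induced regions, where 6600 and 19337 were observed. Its shares are therefore not matched in set size here either. The H363Y ratio was 9.41 without H363Y replicate 2. All sets leave out the same WT peaks, so part of each overlap may come from the shared controls, and intervals cover counting error only.

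pT530-SIRT1 peaks were frequent in WT cells and nearly absent from the KO, labelled as the negative control. WT libraries held 132974 ± 2942 peaks, H363Y libraries 34046 ± 2029 and KO libraries 739 ± 11.3 (SD, n = 2). The log2 difference from WT was -1.97 ± 0.09 for H363Y and -7.49 ± 0.04 for KO. Group explained 0.9999 of the variance (two-sided exact permutation test, p = 0.0667 over 15 partitions, the smallest it can give). The shortest peak of both H363Y lists was exactly 200 bp and that of the WT lists 107 and 111 bp, so this difference in the lists and the genotype cannot be told apart. The KO lists had a mean of 14.5% of their lines on mitochondrial and unplaced contig sequences, where the other 22 ChIP lists of the SIRT1 set had none, so they also differ from the lists they are compared with in what they include. The WT lists had Jaccard indices of 0.623 and 0.626 to pS139-MCM2 KO replicate 2, from cells without SIRT1. Their index to each other was 0.660. Over all MCM2 lists of the SIRT1 set the indices ran from 0.0249 to 0.628, and to the H363Y pT530-SIRT1 lists from 0.106 to 0.127. List size caps this index. The peak positions therefore do not by themselves mark sites particular to SIRT1. Of 112021 pT530-SIRT1 regions called in both WT libraries and neither KO library, the 5 with the widest peaks lay, on hg19, at chromosome 15 from 25419796 to 25499341, chromosome 1 from 2583451 to 2634215, and chromosome 8 from 47084719 to 47121302, from 47312656 to 47343118 and from 47121440 to 47153079. The region on chromosome 1 and the first on chromosome 8 were also touched by a peak in all 8 nascent-strand lists of the SIRT1 set and all 12 of the MCM2 set. These regions were 50765 and 36584 bp wide, and an overlap of 1 bp counted. Their width alone makes such touches likely, and they were not compared with shuffled regions of that width. Of the 22 ChIP lists of the SIRT1 set other than the knockout pT530-SIRT1 lists, 20 had a peak at the chromosome 1 region. At each of the other named regions 11 or 12 did. No filter removed regions that give signal in any assay, and calls alone do not tell these regions from such ones.

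pT530-SIRT1 peaks touched baseline origins more often than the origins induced in both KO and H363Y, once width was taken into account. In WT cells they touched 53.8 ± 0.746% of baseline origins, 5.15 times the share at shuffled positions, and 51.2 ± 0.342% of the wider induced origins, 2.79 times the shuffled share. The width-stratified log2 odds ratio was 0.86 ± 0.10 in WT (SD, n = 2). H363Y peaks touched 29.5 ± 1.55% of baseline and 18.4 ± 1.71% of induced origins, with a log2 odds ratio of 0.85 ± 0.02. The H363Y value differed from WT by -0.01 ± 0.11, within the replicate spread, but not under every setting. H363Y and WT values were 1.30 ± 0.02 and 0.73 ± 0.11 in 2 kb windows, 0.84 ± 0.01 and 0.68 ± 0.03 against aphidicolin-induced origins, and 0.22 ± 0.16 and 0.56 ± 0.04 with the stronger 50% of peaks. Without chromosomes 5, 9, 12 and X they were 0.76 ± 0.01 and 0.55 ± 0.06. In KO lists 1.60 ± 0.0618% of baseline origins and 0 of the 1242 induced origins (Wilson interval up to 0.308% in each list) were touched. The few KO peaks touched baseline origins 26.3 ± 0.971 times as often as shuffled positions, against 10.4 times for H363Y peaks. Without origins at these negative-control peaks the log2 odds ratio was 0.86 in WT and 0.85 in H363Y. This removal took out 266 baseline origins (1.79%) and 0 induced origins, so it could hardly move the ratio. The preference depended on how baseline origins were defined. With untreated WT nascent-strand replicate 1 or replicate 2 left out, every interval of the other one counted as a baseline origin, without the need for 2 calls. Fewer WT peaks were then excluded from induced origins. The WT value was then 0.04 or 0.02, and the H363Y value -0.07 or -0.30. Both values fell beyond their spread whichever of the 2 replicates was left out, which argues against 1 particular library as the whole cause. The looser definition of baseline origins and the fewer excluded WT peaks changed together, so these 2 cannot be told apart.

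Peaks of pS139-MCM2 and pS108-MCM2 favoured baseline origins in 11 of 12 libraries, with a 95% counting interval above 0, when both untreated WT nascent-strand libraries defined the origins. The exception was pS139-MCM2 WT replicate 1, with a log2 odds ratio of 0.13 (-0.06 to 0.32). For pS139-MCM2 the log2 odds ratio was 0.51 ± 0.54 in WT, 1.00 ± 0.19 in KO and 0.96 ± 0.03 in H363Y (SD, n = 2). For pS108-MCM2 it was 1.06 ± 0.19, 0.86 ± 0.26 and 0.75 ± 0.17. The preference fell when 1 of those libraries was left out, which makes every interval of the other a baseline origin. Without replicate 1 of them the 6 group means lay between -0.51 (pS139-MCM2 WT) and 0.34 (pS139-MCM2 KO), and without replicate 2 between -0.17 (pS108-MCM2 KO) and 0.15 (pS139-MCM2 WT). The mean over 6 libraries differed by -0.07 (pS139-MCM2 minus pS108-MCM2), which did not pass (two-sided exact permutation test, p = 0.747). The value turned to 0.07 without pS139-MCM2 WT replicate 1, to 0.13 without untreated WT nascent-strand replicate 2 and to 0.28 with the stronger 50% of peaks. Among the 4 libraries whose shortest peak was exactly 200 bp the difference was -0.36 (exact permutation p = 1, from 2 lists of each antibody, where 0.333 is the smallest possible), and among the 8 others it was 0.07 (p = 0.657).

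pS139-MCM2 peaks were more frequent in both H363Y lists than in both WT lists, and the other genotype differences lay within the replicate spread. pS139-MCM2 lists held 26042 ± 682 peaks in WT, 72459 ± 72526 in KO and 119697 ± 39608 in H363Y. pS108-MCM2 lists held 110832 ± 112476, 64876 ± 58733 and 118960 ± 16092. Over the 6 groups, group explained 0.431 of the variance (two-sided exact permutation test, p = 0.609). Among the 8 libraries without a 200 bp minimum it explained 0.948 (exact permutation p = 0.329). The log2 difference of H363Y from WT was 2.16 ± 0.49 for pS139-MCM2 and 0.62 ± 1.85 for pS108-MCM2, and that of KO from WT was 0.98 ± 1.80 and -0.63 ± 2.41. In covered bases the pS139-MCM2 difference of H363Y was 1.24 ± 1.20, with 55.6 Mb in WT replicate 2, whose median peak width was 1326 bp, and 58.9 Mb in H363Y replicate 2. The KO difference from WT for pS139-MCM2 was -0.32 among lists with a 200 bp minimum and 2.28 among the others, with 1 library on each side. For pS108-MCM2 these values were -0.42 and -0.84. H363Y had no list with a 200 bp minimum. Among the others its difference from WT was 2.19 for pS139-MCM2 and -0.68 for pS108-MCM2, with 2 H363Y lists and 1 WT list.

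Each pS53-MCM2 and pS40/41-MCM2 group had 1 library, so these values have no replicate check. The pS53-MCM2 log2 odds ratio for baseline over induced origins was 0.83 in WT (95% counting interval 0.58 to 1.09), 1.27 in KO (0.83 to 1.71) and 1.19 in H363Y (0.80 to 1.58). For pS40/41-MCM2 it was 0.99 in WT (0.67 to 1.31), 1.27 in KO (0.82 to 1.71) and 0.66 in H363Y (0.39 to 0.92). These values fell when 1 untreated WT nascent-strand library was left out, which makes every interval of the other a baseline origin. Without replicate 1 they lay between -0.32 (pS40/41-MCM2 H363Y) and 0.72 (pS53-MCM2 KO), and without replicate 2 between -0.51 and -0.17. They moved beyond their counting intervals under other settings too. With the stronger 50% of peaks the pS53-MCM2 values were 0.24 in WT, 1.94 in KO and 0.64 in H363Y, and in 2 kb windows 1.57, 2.32 and 2.05. With equal numbers of strongest peaks the KO value was 2.96 for pS53-MCM2, and against aphidicolin-induced origins the H363Y value was 2.94 for pS40/41-MCM2. Baseline origins touched by a peak ranged from 14.3% (13.8% to 14.9%, Wilson) in KO pS53-MCM2 to 25.6% (24.9% to 26.3%) in WT pS53-MCM2.

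**Figure D3:**
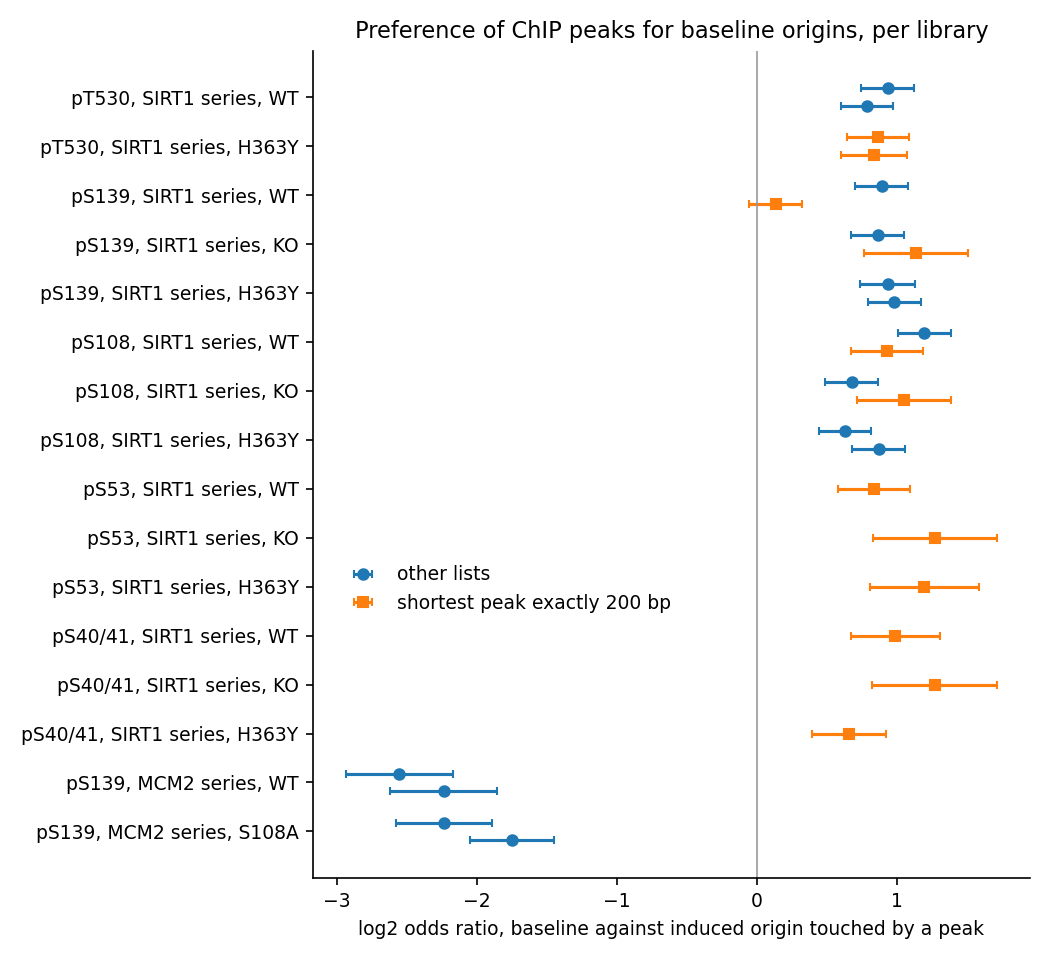
Width-stratified log2 odds ratio of a baseline against an induced origin being touched by a ChIP peak; each point is 1 library, with its 95% counting interval, and squares mark lists whose shortest peak is exactly 200 bp. SIRT1-set libraries lie between 0.13 and 1.27 and MCM2-set libraries between -2.56 and -1.75.

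In MCM2-mAID cells, S139A MCM2 gave the fewest nascent-strand peaks. S139A lists held 29738 ± 819 peaks, against 107422 ± 43542 with WT MCM2, 133526 ± 7555 with S139D, 77750 ± 20825 with S108A, 76885 ± 57462 with S108D and 81905 ± 51180 without add-back (SD, n = 2). The log2 difference from WT MCM2 was -1.79 ± 0.60 for S139A. It was 0.37 ± 0.61 for S139D, -0.43 ± 0.72 for S108A, -0.66 ± 1.34 for S108D and -0.49 ± 1.14 without add-back, each within its replicate spread. Above a common fold enrichment the value without add-back was -1.22 ± 0.42 and that for S108A -0.74 ± 0.45, both beyond the spread. In covered bases the S139D difference was 1.07 ± 0.79, also beyond the spread. Over the 6 groups, group explained 0.652 of the variance (two-sided exact permutation test, p = 0.181). Above that common fold enrichment it explained 0.816 (p = 0.0445, exact permutation). S139A lists also had 0.311 ± 0.0284% of covered bases on chromosome X and 11.6 ± 0.159% on chromosome 5, against 5.02 ± 0.0397% and 5.31 ± 0.539% with WT MCM2.

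**Figure D4:**
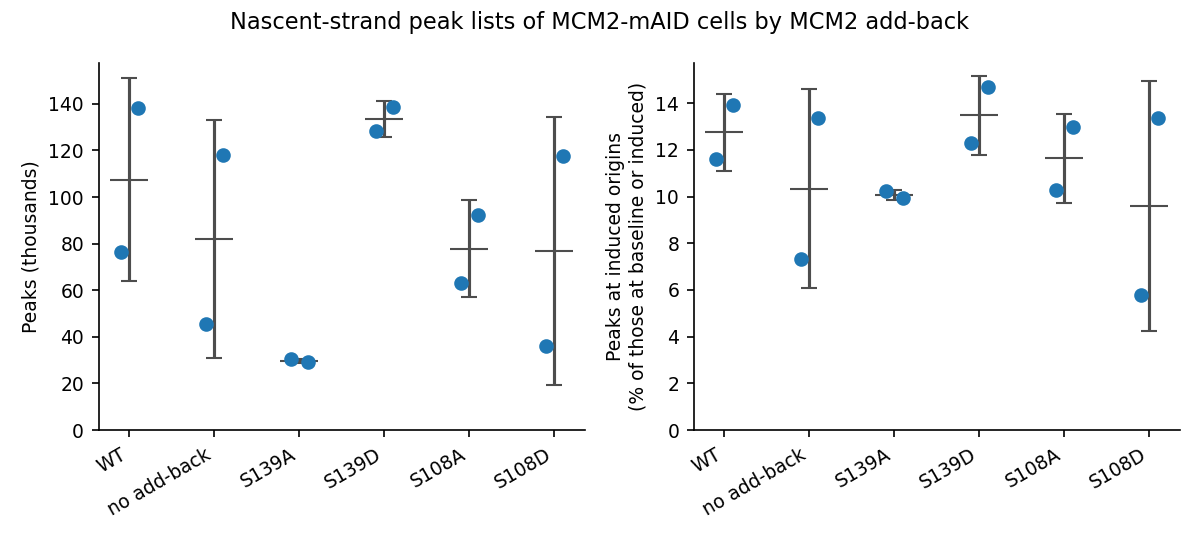
Number of nascent-strand peaks, and peaks at induced origins as a percent of those at baseline or induced origins, for each MCM2 add-back; points are libraries, bars the mean and lines the SD (n = 2). The S139A lists hold 29159 and 30317 peaks, below the other 10 lists.

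Add-backs did not separate in the test over all groups by their share of peaks at origins induced in both KO and H363Y. The share was taken among peaks at baseline or these induced origins. It was 12.8 ± 1.64% with WT MCM2, 13.5 ± 1.69% with S139D, 10.1 ± 0.208% with S139A, 11.7 ± 1.91% with S108A, 9.59 ± 5.36% with S108D and 10.3 ± 4.27% without add-back (SD, n = 2). Group explained 0.305 of the variance (two-sided exact permutation test, p = 0.754). The S139A difference from WT MCM2 was -2.68 ± 1.66 percentage points and turned to 1.19 ± 0.541 with the same number of strongest peaks per list. It was -0.885 without untreated SIRT1-set WT replicate 1, -5.49 without H363Y replicate 2 and -1.52 without WT MCM2 replicate 2, and -6.77 without chromosomes 5, 9, 12 and X. S139D lists touched 78.9 ± 0.647% of baseline and 97.0 ± 1.08% of induced origins, and S139A lists 30.8 ± 2.82% and 35.7 ± 3.59%. These shares were not adjusted for origin width or list size, nor compared with shuffled positions. Induced origins were wider (median 3329 bp against 1095 bp). S139D lists covered 84.7 and 146 Mb, and S139A lists 10.1 and 11.9 Mb. The shares therefore do not show which kind of origin an add-back favoured or lost.

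Replicates of an add-back were more alike than libraries of different add-backs, by 0.0877 in mean Jaccard index (two-sided exact permutation test, p = 0.0203). The index between replicates was 0.411 for S139D, 0.346 for WT MCM2, 0.311 for S108A and 0.211 for S139A. It was 0.141 without add-back and 0.0756 for S108D, whose replicate 2 shared 0.512 with S139D replicate 1. List size caps this index. The S108D lists covered 14.3 and 134 Mb and S139D replicate 1 covered 146 Mb, so the low S108D value and part of the test result may reflect list size. The call was lost without WT MCM2 replicate 1 (0.0583, exact permutation p = 0.195) or replicate 2 (0.0707, p = 0.0949). It was also lost without S139D replicate 1 (0.0577, exact permutation p = 0.109) or replicate 2 (0.0601, p = 0.151), and without S108A replicate 1 (0.0789, p = 0.0732).

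pS139-MCM2 ChIP peaks in MCM2-mAID cells were many and short. Lists held 445170 ± 27960 peaks with WT MCM2 and 364444 ± 37077 with S108A MCM2 (SD, n = 2), a log2 difference of -0.29 ± 0.17 (two-sided exact permutation p = 0.333, the smallest 2 against 2 can give). They touched 95.1 ± 0.0569% of induced and 65.5 ± 2.15% of baseline origins with WT MCM2, and 92.6 ± 1.65% and 62.9 ± 0.903% with S108A. The log2 odds ratio was -2.40 ± 0.22 with WT MCM2 and -1.99 ± 0.34 with S108A, below 0 in all 4 libraries. Relative to shuffled positions of the same widths the order was opposite: WT MCM2 peaks touched baseline origins 3.58 ± 0.0592 times and induced origins 2.81 ± 0.157 times as often, and S108A peaks 4.07 ± 0.369 and 3.14 ± 0.0839 times. Nearly all induced origins were touched, so neither measure settles which kind of origin was favoured. The S108A value differed by 0.40 ± 0.41 (exact permutation p = 0.333), within the replicate spread. It was beyond the spread under some settings, at 0.11 ± 0.02 against aphidicolin-induced origins, 0.65 ± 0.57 at least 5 kb from WT peaks, 0.72 ± 0.68 with the stronger 50% of peaks and 0.39 ± 0.36 with an overlap of 50%. With equal numbers of strongest peaks it was 0.10 ± 0.31.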

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

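Of the tests in this part, those on weak peaks, on baseline-origin summits and on list class by measures meant to take size out were set before their results were seen. The other test on list class and those on antibody, genotype, shared regions and chromosome X were chosen after. Peak numbers in H363Y differed from WT in opposite directions for pT530-SIRT1 and pS139-MCM2: both H363Y lists lay below both WT lists for pT530-SIRT1 and above both for pS139-MCM2, a gap of 4.13 on the log2 scale. This difference was not tested, and both H363Y lists of pT530-SIRT1 have a 200 bp minimum while those of pS139-MCM2 do not. Per the labels, pT530-SIRT1 ChIP also used asynchronous cells and MCM2 ChIP cells held at the G1/S boundary. Antibody, cell-cycle state and list class cannot be told apart in this gap. On mitochondrial and unplaced contig sequences, left out of all comparisons, nascent-strand lists had up to 1.61% of their lines and the pT530-SIRT1 knockout lists a mean of 14.5%, while the other 22 ChIP lists of the SIRT1 set had none.

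ChIP lists of pS139-MCM2 and pS108-MCM2 fell into 2 classes, 4 lists whose shortest peak was exactly 200 bp (21175 to 31300 peaks, 12.2 to 19.995 Mb) and 8 others (25559 to 190365 peaks, 55.6 to 106 Mb). Lists of 1 class were more alike than lists of different classes by 0.265 in mean Jaccard index (exact permutation p = 0.00202), but list size caps that index, so the value decides nothing. The part of the smaller list's bases that was shared was 1.14 percentage points higher within classes (exact permutation p = 0.822). Size does not cap this share, but a larger partner list can raise it. Pairs of different classes always set a list of 12.2 to 19.995 Mb against one of 55.6 to 106 Mb, so this value cannot decide either. The Jaccard index of the 21175 widest peaks of each list was higher by 0.162 within classes (exact permutation p = 0.00202). These peaks still cover 12.2 to 18.4 Mb in the first class and 26.2 to 53.8 Mb in the other. By these indices, a calling setting or batch, antibody (-0.0229, exact permutation p = 0.587) and SIRT1 genotype (0.0304, exact permutation p = 0.448) cannot be told apart. Nor can the last 2 together as the whole cause (0.101, an overlap of index ranges that size also caps). In 4 groups of 1 antibody and 1 genotype, however, the 2 replicates fell into different classes. These lists covered 12.2 to 19.995 Mb in the first class and 55.6 to 106 Mb in the other. Peak number was also higher in the other class, except for pS139-MCM2 WT (26524 against 25559). These values argue against antibody and genotype, alone or together, as the whole cause of the split, but not as part of it. H363Y had no list in the first class. Contrasts of pT530-SIRT1 between H363Y and WT lie along the same split, so setting and genotype cannot be told apart there.

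KO nascent-strand lists held 4.98 and 3.34 peaks per interval against 1.80 and 1.65 in WT, while the difference in intervals (-0.20 ± 0.50 on the log2 scale) lay within the replicate spread. Among the 66999 strongest peaks of each list these values were 2.89 and 1.98 against 1.72 and 1.47, so most of the KO excess went with the weaker peaks, but the lower KO list still held 0.266 more than the highest of the other 6, which argues against weak peaks as the whole cause only. More summits inside baseline origins were predicted and not seen (-0.50 summits per kb, lower KO list minus higher WT list), but that bound was ill chosen, since WT calls alone select and bound those regions and 52.7% of them were called in both KO libraries. In regions called in both groups the difference was 0.744, which restates the larger KO peak number, since these regions held 39.9% and 40.2% of all summits in KO and 44.0% and 29.5% in WT. Denser initiation inside shared origins, a biological hypothesis, and depth, which the lists do not show, thus stay open and undecided by these values.

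Chromosome X held 0.291% and 0.331% of covered bases in S139A lists and 0.458% and 0.503% under aphidicolin. Its share was lower in 100% of the 16 bins of 10 Mb under aphidicolin than in untreated WT, and in 100% with S139A than with WT MCM2, but the low totals nearly fix that outcome, so a technical offset of the chromosome, such as the control used in calling, and an effect of the treatment cannot be told apart. Add-back explained 0.968 of the variance of the log2 X share (exact permutation p = 0.0278), and the lowest other MCM2-set list exceeded the higher S139A list by 2.79 percentage points. For the S139A lists, add-back and list preparation cannot be told apart, since both lists share them. The 2 S108D lists differed by 5.36 percentage points against an SD of 2.57 between group means, but S108D was picked for that gap, so the add-back stays open there.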

How the results depend on the processing

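Alternatives with distinct intervals, summit windows, chromosomes 5, 9, 12 and X removed, negative-control peaks removed and a split by shortest peak, and leaving out untreated WT replicates for single MCM2 ChIP preferences, were chosen after the data were seen; all others were set before. Of the values recomputed under alternatives, 367 kept their direction and their side of the threshold or stayed within the spread, 98 moved by more than the spread, 24 reversed, 5 gained a call and 6 lost one. A contrast smaller than its spread was not counted as reversed, a rule narrowed after the first results. Several such contrasts changed sign, for example pS108-MCM2 peak number in KO minus WT, from -0.63 to 0.67 without pS108-MCM2 WT replicate 2. Gene lists and genes at origins were not run, since no hg19 annotation was used. Depth limits every count, as the lists hold no reads. The cause of the changes below was not tested, except where the construction shows it: leaving out a replicate ends the need for 2 calls and raises counts of induced origins. Leaving out an untreated WT replicate also makes every interval of the other one a baseline origin.

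With covered bases in place of peaks, the share of variance between SIRT1 groups was 0.886 (exact permutation p = 0.0286). The log2 difference from WT was then 1.28 for KO and 0.78 for H363Y, -2.51 for H363Y and -6.86 for KO in pT530-SIRT1, 1.24 for H363Y in pS139-MCM2, and 1.07 for S139D. Above a common strength the differences were 1.71 for KO, -0.041 for H363Y and 0.59 for aphidicolin, and for pT530-SIRT1 -2.63 in H363Y and -7.15 in KO. The share between MCM2 add-backs was 0.816 (exact permutation p = 0.0445). With peaks within 1 kb merged, the differences were -0.33 for KO and 0.52 for aphidicolin, and for pT530-SIRT1 -1.58 and -7.78. With distinct intervals the KO difference was -0.20.

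With the stronger 50% of peaks, induced origins numbered 3803 in KO, 2951 in H363Y and 11053 under aphidicolin, and the KO to H363Y overlap was 23.3 times the shuffled one. The pT530-SIRT1 preference was 0.56 in WT and 0.22 in H363Y, the pS139-MCM2 minus pS108-MCM2 difference 0.28, the pS53-MCM2 preference 0.24 in WT, 1.94 in KO and 0.64 in H363Y, and the pS40/41-MCM2 preference 0.21 in WT and 0.17 in H363Y. At least 5 kb from WT peaks, induced origins numbered 3580, 2405 and 12360, overlap ratios were 35.8 (H363Y) and 12.8 (aphidicolin), and the H363Y pT530-SIRT1 preference was 0.70. With summit windows, KO gave 18760 induced origins and the H363Y overlap ratio was 23.2. With equal numbers of strongest peaks, H363Y gave 3235 induced origins and overlap ratios were 21.3 and 9.57. Preferences were then 0.46 (WT) and 0.47 (H363Y) for pT530-SIRT1, 0.45 (WT) and 2.96 (KO) for pS53-MCM2 and 1.93 (KO) for pS40/41-MCM2, and the antibody difference was 0.18. The induced share differed from WT MCM2 by 1.19 points for S139A and 3.30 for S139D. With an overlap of 50%, overlap ratios were 26.5 and 10.9.

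In 2 kb windows the pT530-SIRT1 preference was 0.73 in WT and 1.30 in H363Y, that of pS53-MCM2 1.57, 2.32 and 2.05 and that of pS40/41-MCM2 1.78, 2.44 and 1.47 (WT, KO, H363Y). Against aphidicolin-induced origins, values were 0.68 for pT530-SIRT1 in WT, 0.11 for the antibody difference and 2.94 for pS40/41-MCM2 in H363Y. Without chromosomes 5, 9, 12 and X, they were 0.55 (WT) and 0.76 (H363Y) for pT530-SIRT1, and S139A differed from WT MCM2 by -6.77 points. Among lists without a 200 bp minimum the antibody difference was 0.073.

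Leaving out 1 replicate at a time, the share of variance between SIRT1 groups ranged from 0.838 to 0.987 and the similarity difference from 0.0961 (without KO replicate 1) to 0.197, and that of the MCM2 set from 0.0577 to 0.136. Induced origins ranged from 8305 to 22504 in KO, from 10555 to 34340 in H363Y and from 22851 to 45901 under aphidicolin, and overlap ratios from 9.41 (without H363Y replicate 2) to 17.3 with H363Y and from 7.22 to 10.3 with aphidicolin. The pT530-SIRT1 preference ranged from 0.020 to 1.11 in WT and from -0.30 to 1.11 in H363Y, where it was -0.07 and -0.30 without untreated WT replicates 1 and 2. The antibody difference ranged from -0.13 to 0.13, with 0.07 without pS139-MCM2 WT replicate 1 and 0.13 without untreated WT replicate 2. Without untreated WT replicates 1 and 2 the preferences were -0.51 and 0.15 (WT), 0.34 and -0.11 (KO) and 0.27 and 0.046 (H363Y) for pS139-MCM2, 0.29 and -0.078, 0.074 and -0.17, and 0.015 and -0.050 for pS108-MCM2, -0.028 and -0.45, 0.72 and -0.37, and 0.54 and -0.17 for pS53-MCM2, and 0.13 and -0.36, 0.46 and -0.28, and -0.32 and -0.51 for pS40/41-MCM2. The S139A difference in induced share ranged from -5.49 points (without H363Y replicate 2) to -0.885 points (without untreated WT replicate 1).

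Samples share only a replicate number. In WT and KO of pS139-MCM2 and pS108-MCM2, the replicate 1 lists are the 4 with a 200 bp minimum and the replicate 2 lists are not. Replicate number and list class cannot be told apart there. Correlations of same-numbered deviations ran from -0.207 to 0.347 in the SIRT1 nascent-strand set from -0.371 to 0.714 in the MCM2 set and from -0.53 to 0.849 for pS139-MCM2 and pS108-MCM2 ChIP, and the single value for pS139-MCM2 ChIP of the MCM2 set was 0.60. With the replicate number as a block, group explained 0.82 of the variance of MCM2-set peak number (exact permutation p = 0.0347), against p = 0.181 without the block. The S108A minus WT MCM2 difference in pS139-MCM2 preference had a spread of 0.41 without and 0.12 with the block, around 0.40. The other blocked tests kept their side of the threshold. For SIRT1 peak number the blocked share was 0.921 (exact permutation p = 0.167).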

Other observations

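Induced origins lay nearer to baseline origins than shuffled positions did, an observation made after seeing the data. KO-induced origins had a median distance of 39.1 kb to the nearest baseline origin, against 277 ± 7.52 kb for 100 shuffles within chromosomes outside WT peaks. H363Y-induced origins had 23.3 kb against 200.2 ± 6.13 kb, and aphidicolin-induced origins 64.5 kb against 269 ± 4.62 kb. Of the 14873 baseline origins, 11.6% were called in all 12 lists of the MCM2 set and 3.53% in none. Of the 1242 origins induced in both KO and H363Y, 12.1% were called in all 12 and 0.0805% in none.

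A hypothesis that this proximity only reflects clustering of nascent-strand peaks, reproducible or not, was tested with KO peaks called in 1 replicate that touch no WT peak, a test set before its result was seen. Of these 16156 peaks, 20.1% lay within 10 kb of a baseline origin, against 23.3% of KO-induced origins and 6.49 ± 0.194% when shuffled. Clustering shared by peaks seen once may therefore account for part of the proximity, and this test does not decide whether it accounts for all of it. Shuffles did not avoid assembly gaps, which lowers the shuffled share by an amount not measured here.

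The negative-control lists of pT530-SIRT1 in the knockout merged into 834 regions. Of these, 28.5% touched a baseline origin and 17.4% a pT530-SIRT1 peak of WT cells, and 266 baseline origins (1.79%) touched one.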
